A study of Homo sapiens with 2 samples.

How the data were processed

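RNA sequencing was done on 2 libraries of HCT116 cells, 1 infected with the empty vector and 1 with the shRNA against SETDB1. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit for Illumina. The submitters' processing notes name CASAVA, HISAT2, featureCounts 1.5.0-p3 and the build GRCh38, without their roles. The annotation release, the strand setting, the treatment of multi-mapped reads and whether poly(A) RNA was selected are not given in the sources used here. Without strand in the counting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies can be lost or split.

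The authors deposited 1 value per gene and library in FPKM (fragments scaled by gene length and by the library total), with the gene length they divided by. The table holds 61403 rows, of which 19966 are protein-coding and 20794 have no gene name. Identifiers of another form than Ensembl's are in 739 rows, and 527 of these lie on alternate contigs. Some genes that most cells express abundantly were at very low values (HLA-B at 0 and 0.0695 FPKM, CANX at 1.22 and 0.872 FPKM) and HSPA1A was listed at 0 in both libraries, so a low value of a gene with overlapping genes or alternate contigs is not evidence of low expression. These genes were chosen after their values were seen.

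FPKM times gene length was a whole multiple of a constant in each library, within 0.01 for 100% of values, so the number of fragments per gene was recovered from the deposited FPKM values. They summed to 14930201 in the control and 12790965 in the knockdown library. The constants correspond to scaling totals of 17808428 and 14324624 fragments, of which the summed genes make up 83.8% and 89.3%. The recovered fragments served for exact intervals: Poisson intervals for a level and conditional binomial (Clopper-Pearson) intervals for a ratio, both at 95%. Fragments carry no molecular identifiers, so copies made by amplification can count as separate fragments. Intervals and floors (3 fragments) cover counting error of fragments only, and the intervals can be too narrow. Protein-coding genes took 95.7% and 96.4% of fragments, and the 10 most abundant genes 8.74% and 9.87%.

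With 1 library per group no test was possible, and no p-value is given. Genes were described by a fixed rule of size: a difference of at least 2-fold in log2((knockdown + 1) / (control + 1)), with a pseudocount of 1 FPKM, among protein-coding genes with a mean of at least 1 FPKM. The following were fixed before the data were examined: this rule, 36 gene lists, the alternatives and the rule for named genes. That rule took SETDB1, the 12 highest and 12 lowest protein-coding genes with a mean of at least 5 FPKM, and for each list up to 4 members with the largest absolute log2 ratio among those with a mean of at least 1 FPKM. The lists of H3K9 machinery, Wnt, neural stem and neuronal genes could be named member by member. Some genes that the rule takes are not reported here. Each list's median log2 ratio over members past the filter was set as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 measured members stood apart at a percentile of at most 2.5 or at least 97.5. Lists overlap, for example BBC3 is in the p53 and apoptosis lists, ATF3 in the immediate early and unfolded protein response lists, and UHRF1 in the replication and H3K9 lists.

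Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, equal FPKM totals, centring on the median, all annotated genes, and rules of 1.5-fold and 4-fold. Removal of the lowess trend with GC content and length was added after the data were seen. So was a fit without genes under 50 fragments over both libraries or overlapping another gene with reads on the same strand. Genes overlapped only on the other strand stayed in that fit. Also added then was a comparison of the chromosome 19 zinc finger list with random lists of the other genes of that chromosome, matched on expression in 10 bins. GC content was had for 99.9% of the protein-coding genes past the filter. Gene names and coordinates are those of the deposited table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

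The scripts were tested on simulated data drawn from both libraries' means, with 10232 genes in the step. The 2-fold rule recovered 50 of 50 genes made 3-fold higher, 42 of 50 made 3-fold lower, 50 of 50 made 8-fold higher and 43 of 50 made 8-fold lower, and took 0 of 10043 unchanged genes. The step held 189 of the 200 changed genes, since 11 made lower fell under the expression filter: of those made 3-fold and 8-fold lower, 46 and 43 stayed in it. Ratio intervals held the true ratio for 96.25% of genes. For the lists, each gene was given its own random fold, drawn independently of the other genes. Of 200 random lists without a shared shift, 9 stood apart, and a list shifted 2-fold lay at percentile 100. This does not give the rate for lists whose genes vary together.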

Results

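Transcript levels were measured by RNA sequencing in HCT116, a human colorectal cancer cell line. Cells had been infected with a lentivirus that carried either the empty shRNA vector pLKO.1 (empty vector control, 1 library) or an shRNA directed at SETDB1 (SETDB1 knockdown, 1 library), and were cultured for 5 days. SETDB1 is a histone methyltransferase that trimethylates lysine 9 of histone H3, a mark of silent chromatin. The control library held 14930201 fragments assigned to genes and the knockdown library 12790965, with 25663 and 23980 genes above 0. The median fragment count of a protein-coding gene past the expression filter was 657 in the control and 548 in the knockdown library. A floor of 3 fragments corresponded to 0.168 FPKM in the control and 0.209 FPKM in the knockdown library for a gene of 1 kb. Levels below are FPKM values, and folds are ratios of FPKM with 95% intervals in parentheses that cover counting error only. Each group has 1 library, so no difference has a replicate check, no test was run, and each comparison is between these libraries and not between the conditions.

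The comparison asks which transcripts differ in level when SETDB1 is knocked down, and the target itself was read first. SETDB1 (ENSG00000143379, GRCh38 chromosome 1, 150926263 to 150964744, plus strand) was at 5.83 FPKM in the control library and 0.463 FPKM in the knockdown library, from 736 and 47 fragments. It was 12.6-fold lower in the knockdown library (9.37 to 17.3), which left 7.94% of the control level (5.78 to 10.7). The library labelled as the knockdown was thus the library with less SETDB1 mRNA.

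The genes at the upper end of the log2 ratio were led by CPA4, a secreted carboxypeptidase (ENSG00000128510, chromosome 7, 130293134 to 130324180). CPA4 was at 0.695 FPKM in the control and 42.3 FPKM in the knockdown library, a 60.8-fold difference (45.9 to 82.5). The histone genes H2BC5 and H1-2 followed, 19.7-fold (14.9 to 26.7) and 16.7-fold (13.8 to 20.5) higher. ARF4, a small GTPase of Golgi vesicle traffic (ENSG00000168374, chromosome 3, 57571363 to 57598220), was at 44.0 FPKM in the control and 595 FPKM in the knockdown library (13.5-fold, 12.9 to 14.2). CREB3, a membrane-bound transcription factor that is cleaved at the Golgi, was 8.47-fold higher (7.66 to 9.39). The stress-response transcription factors JUN and ATF3 were 14.5-fold (13.0 to 16.2) and 12.1-fold (10.6 to 14) higher. HERPUD1, a protein of endoplasmic reticulum-associated degradation, was 11.4-fold higher (10.6 to 12.3), and LAMB3, a laminin chain of epithelial basement membrane, 11.5-fold higher (10.8 to 12.3). PGK1, a glycolytic enzyme (ENSG00000102144, chromosome X, 77910739 to 78129295), was at 86.7 FPKM in the control and 805 FPKM in the knockdown library (9.29-fold, 9.08 to 9.50). TMEM40 and ARL14EPL completed the 12 highest genes, at 19.9-fold (15.4 to 26.2) and 16.6-fold (13.2 to 21.3).

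At the lower end stood ABHD14B (7.92-fold lower, 6.51 to 9.72) and several genes of proliferating cells. DEPDC1B was 10.5-fold lower (8.01 to 14.1), HMMR, a spindle-associated hyaluronan receptor, 9.66-fold lower (7.54 to 12.6), and MKI67, which encodes the proliferation marker Ki-67, 5.04-fold lower (4.79 to 5.31). KITLG, the ligand of the receptor KIT, was at 233 FPKM in the control and 44.3 FPKM in the knockdown library (5.25-fold lower, 5.08 to 5.43). S100A6, a calcium-binding protein, was at 645 and 134 FPKM. The gap junction gene GJA1 was 6.18-fold lower (5.22 to 7.38), and VDAC1, the outer mitochondrial membrane channel, 4.84-fold lower (4.48 to 5.23). PI4K2B, WDR76 and UHMK1 were 7.48-fold, 7.32-fold and 5.38-fold lower.

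**Figure D1:**
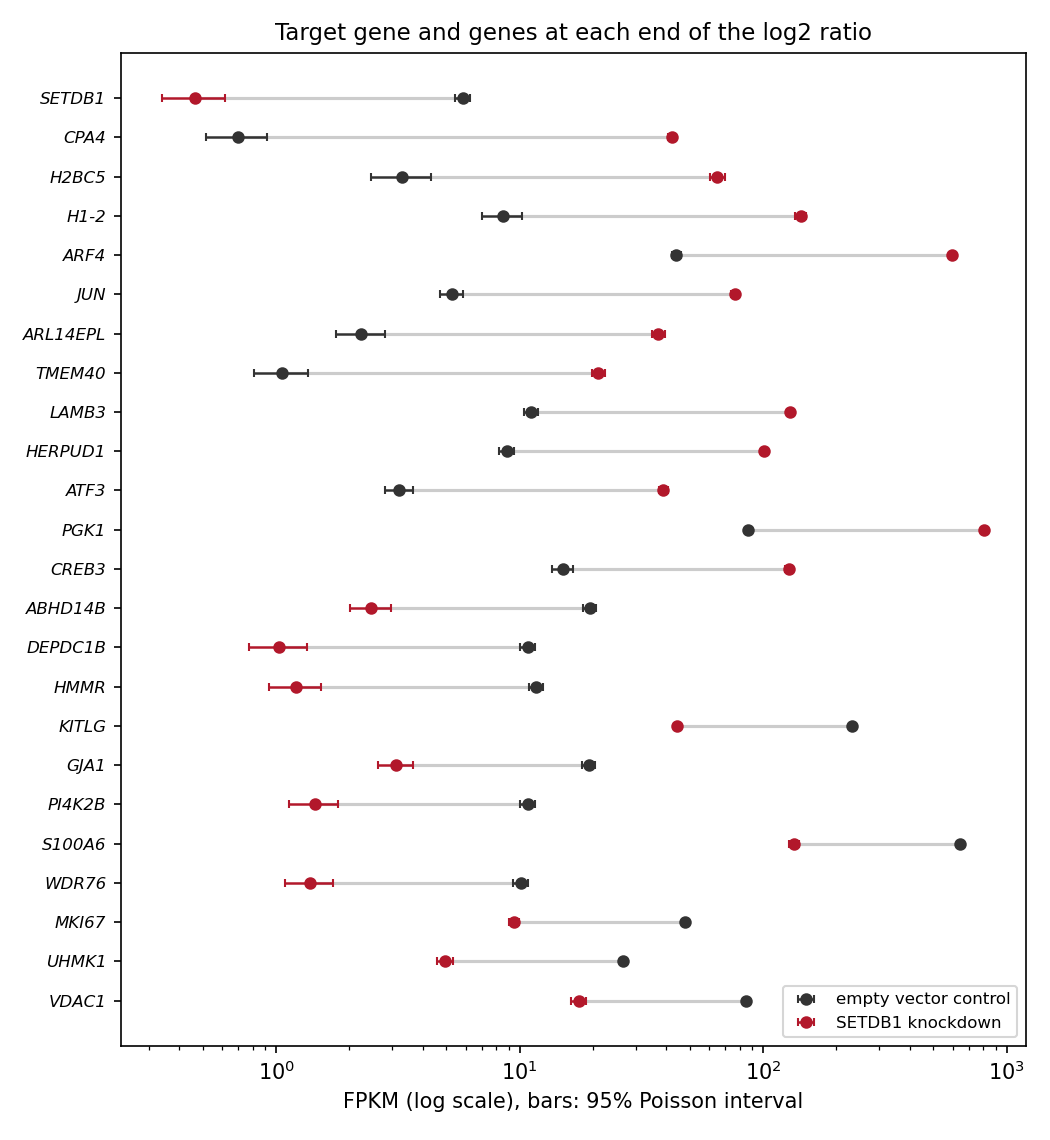
FPKM (log axis) of SETDB1 and of genes among the 12 highest and 12 lowest protein-coding genes by log2 ratio in the empty vector control library (dark) and the SETDB1 knockdown library (red), with 95% Poisson intervals of each library's count as bars. SETDB1 lies at 5.83 and 0.463 FPKM and CPA4 at 0.695 and 42.3 FPKM, and no pair of intervals overlaps.

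Across the 10249 protein-coding genes with a mean of at least 1 FPKM, 822 (8.02%) were at least 2-fold higher in the knockdown library and 657 (6.41%) at least 2-fold lower, on the log2(FPKM + 1) scale, which understates the ratio of low genes. Counts of list members at least 2-fold higher or lower are on the same scale. The remaining 8770 lay between. Of the genes past 2-fold, 55.6% were higher, but this split depended on scaling. It was 42.1% when both libraries were set to the same FPKM total and 44.5% when they were centred on the median, with log2 shifts of -0.14 and -0.10. In 20 simulated pairs of libraries that differed by counting error alone, at most 1 gene passed 2-fold. The log2 ratio had an SD of 0.71 across genes, and the libraries correlated at Pearson's r = 0.883 across genes, which are not independent replicates.

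**Figure D2:**
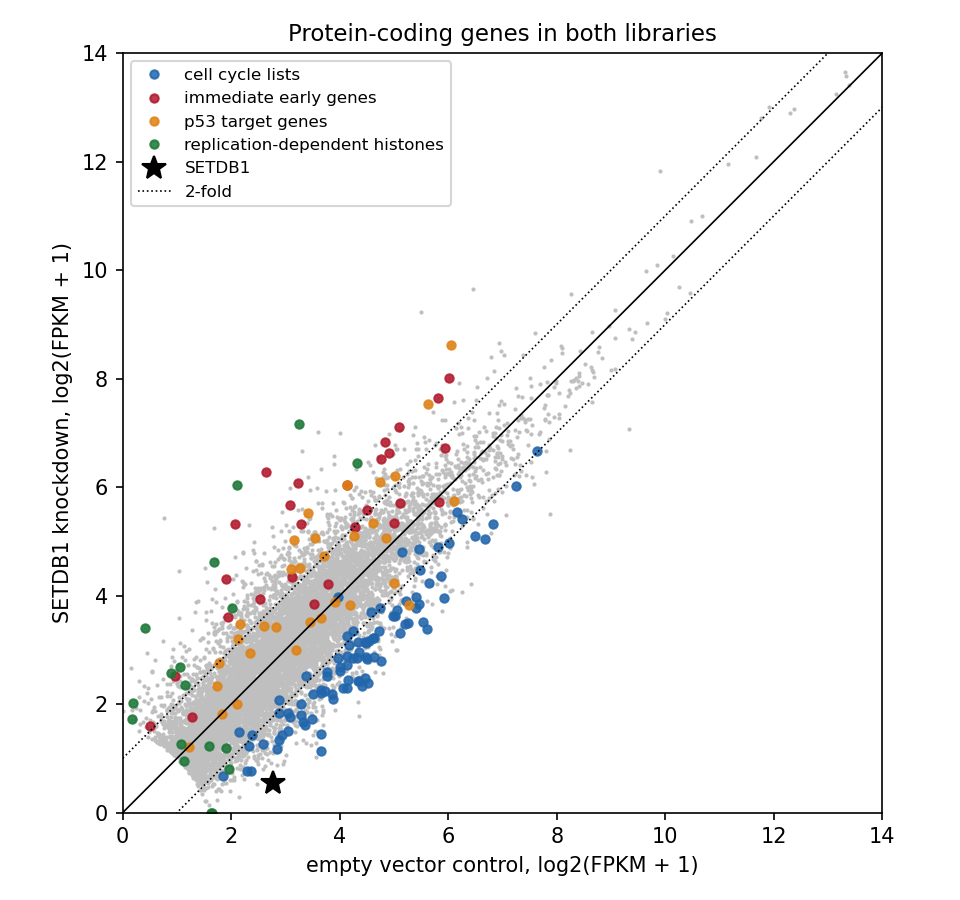
log2(FPKM + 1) of named protein-coding genes with a mean of at least 1 FPKM in the empty vector control library (x axis) and the SETDB1 knockdown library (y axis), where each point is a gene, the solid line marks equal levels and the dotted lines a 2-fold difference. The cell cycle lists (blue) lie mostly below the lower dotted line and the immediate early genes (red) mostly above the upper one.

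Genes of cell division formed the group most lower in the knockdown library. Of 43 measured G2/M and mitotic genes, 36 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -1.39. Besides HMMR and MKI67, the kinetochore protein gene CENPF was 5.25-fold lower (4.85 to 5.69) and the spindle checkpoint kinase gene BUB1B 4.43-fold lower (3.89 to 5.04). Of 48 measured DNA replication and E2F target genes, 39 were at least 2-fold lower and 0 higher, with a median of -1.41. The replication initiation factors MCM10 and CDC6 were 6.67-fold (5.58 to 8.04) and 5.01-fold (4.44 to 5.67) lower, and the helicase subunit MCM6 4.35-fold lower (3.99 to 4.74). Both medians lay below those of all 10000 random lists of equal size and expression (percentile 0), a description of these libraries.

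Targets of p53 were higher as a group, with a median log2 ratio of 0.78 over 32 measured members (percentile 100), of which 13 were at least 2-fold higher and 1 lower. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 65.7 FPKM in the control and 392 FPKM in the knockdown library (5.96-fold, 5.75 to 6.18). PLK2, the antiproliferative gene BTG2 and the stress cytokine gene GDF15 were 4.68-fold (4.33 to 5.07), 3.89-fold (3.59 to 4.21) and 3.79-fold (3.59 to 4.0) higher. Other targets went the other way: CCNG1, the member at least 2-fold lower, was 2.87-fold lower (2.62 to 3.15), FDXR 1.74-fold (1.61 to 1.88) and MDM2, which encodes the ubiquitin ligase of p53, 1.31-fold lower (1.23 to 1.39), all 3 chosen after their values were seen. Among 27 measured apoptosis genes, 4 were at least 2-fold higher and 0 lower (median 0.42, percentile 99.05). They were BAK1 (2.87-fold, 2.57 to 3.21), PMAIP1 (2.80-fold, 2.58 to 3.04), BBC3 (2.80-fold, 2.5 to 3.15) and TNFRSF10B (2.32-fold, 2.22 to 2.43), which encode promoters of the mitochondrial and death receptor pathways. The p53 and apoptosis lists share genes, BBC3 and TNFRSF10B among them, and the apoptosis list no longer stood apart with a pseudocount of 5 (percentile 95.1), with no filter on low values (96.2) or with a filter at 5 FPKM (95.2).

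Immediate early genes, which respond within minutes to growth factors and stress, had the highest median of the lists with a pseudocount of 1. The replication-dependent histones had a similar median, and a higher one under several other settings, such as 2.11 against 1.85 with a pseudocount of 0.1. Of 27 measured immediate early genes, 19 were at least 2-fold higher and 0 lower (median 1.66, percentile 100). Beside JUN and ATF3, the phosphatase gene DUSP1 was 7.89-fold higher (6.99 to 8.94) and CCN1, a matrix protein and target of the YAP coactivator, 6.62-fold higher (6.01 to 7.31). Among 30 measured genes of the unfolded protein response and of ATF4, 12 were at least 2-fold higher and 0 lower (median 0.41, percentile 97.9). DDIT3, the stress transcription factor CHOP, was at 3.22 FPKM in the control and 25.2 FPKM in the knockdown library (7.82-fold, 6.12 to 10.1), and CHAC1, a glutathione-degrading enzyme, was 7.38-fold higher (6.13 to 8.92). This list's median stood apart only narrowly: it lost that place under every other setting except centring, down to a percentile of 51.3 and a median of 0.11 without low-count and overlapping genes.

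Cholesterol biosynthesis genes were lower as a group. Of 25 measured members, 4 were at least 2-fold lower and 0 higher (median -0.50, percentile 0.02). Among these were ACAT2, an acetyl-CoA acetyltransferase at the start of the pathway (3.49-fold lower, 2.84 to 4.32), INSIG1, a sterol-regulated retention factor of SREBP (3.0-fold lower, 2.64 to 3.41), and EBP, a sterol isomerase (2.32-fold lower, 1.88 to 2.87). Hypoxia and glycolysis genes did not stand apart (median -0.01 over 32 members, percentile 29.3), with 5 members at least 2-fold higher and 1 lower. Beside PGK1, ANGPTL4 was 4.28-fold higher (3.71 to 4.96), P4HA2 2.85-fold higher (2.57 to 3.16) and ALDOA 4.10-fold higher (3.27 to 5.17), the last from a level of 1.48 FPKM in the control that is low for this abundant enzyme. Heat shock genes did not stand apart (median -0.34 over 16 members, percentile 2.91), with 1 at least 2-fold higher and 0 lower, and their median turned to 0.17 over 11 members (percentile 67.2) without low-count and overlapping genes. The abundant chaperones HSP90AB1, HSP90AA1 and HSPD1 were 1.86-fold (1.83 to 1.88), 1.87-fold (1.84 to 1.90) and 2.0-fold (1.95 to 2.05) lower, while DNAJB4 was 3.16-fold higher (2.83 to 3.55).

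Among other genes of H3K9 methylation and its readers, 3 of 19 measured members were at least 2-fold lower and 1 higher (median -0.53, percentile 0.1). UHRF1 and DNMT1, which maintain DNA methylation through replication, were 3.27-fold (3.04 to 3.52) and 2.26-fold (2.15 to 2.37) lower, and CBX5, the heterochromatin protein HP1 alpha, 2.94-fold lower (2.78 to 3.11). SUV39H1 and SUV39H2, other H3K9 methyltransferases, were 1.90-fold (1.49 to 2.43) and 1.86-fold (1.55 to 2.23) lower, and TRIM28, the corepressor that recruits SETDB1 to zinc finger proteins, 1.60-fold lower (1.56 to 1.65). MBD1, a methyl-CpG binding protein, was 3.06-fold higher (2.85 to 3.29), and ATF7IP, the stabilising partner of SETDB1, 1.93-fold higher (1.77 to 2.10). The HUSH complex genes went both ways, with TASOR 1.65-fold lower (1.5 to 1.82), MORC2, which works with the complex, 1.68-fold higher (1.54 to 1.84), and MPHOSPH8 and PPHLN1 at 1.03-fold. EHMT2 was listed at 0 in both libraries, as was HSPA1A, and such a value alone is not evidence of low expression. Polycomb genes had a median of -0.24 over 26 members (percentile 2.6, and 2.49 with equal FPKM totals, past the limit), with JARID2 3.34-fold higher (3.07 to 3.64) and the methyltransferase gene EZH2 2.0-fold lower (1.84 to 2.18). Of these 26, 1 was at least 2-fold higher and 2, PCGF6 and CBX6, at least 2-fold lower.

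Zinc finger genes on chromosome 19, whose clusters carry H3K9 trimethylation in many cell types, were higher by a small amount. Their median log2 ratio was 0.22 over 113 measured members (percentile 100), with 4 at least 2-fold higher and 0 lower, and was 0.12 with equal FPKM totals or centring. Chromosome 19 as a whole had the highest median of the 23 chromosomes, 0.14 over 733 genes. Its 620 other genes had a median of 0.12, and against random lists drawn from these the zinc finger list lay at percentile 99.3, a comparison added after the data were seen. ZNF274, a KRAB zinc finger gene whose product recruits SETDB1, was 5.53-fold higher (4.68 to 6.58), ZNF559 3.02-fold (2.47 to 3.71) and ZNF417 2.73-fold higher (2.26 to 3.32). The other member past 2-fold on the log2(FPKM + 1) scale, ZFP36 (4.11-fold, 3.82 to 4.42), encodes an mRNA decay protein with no KRAB domain and is also an immediate early gene. With a filter at 5 FPKM, 17 members were left and the list no longer stood apart (median 0.45, percentile 96.3). With no filter on low values its median was 0.07 over 182 members (percentile 100). Zinc finger genes elsewhere had a median of 0.02 over 191 members (percentile 85.3), with 4 at least 2-fold higher, ZNF697 and ZNF513 among them, and 2 lower, ZNF704 and ZNF367. Their median was -0.10 with equal FPKM totals, -0.08 with centring and -0.004 with no filter on low values.

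Other classes that SETDB1 silences in various systems were mostly near the detection limit. Of 53 clustered protocadherin genes, 1 passed the filter: PCDHGA10 was at 0.888 FPKM in the control and 2.67 FPKM in the knockdown library (3.01-fold, 2.39 to 3.81). Summed over all 53, protocadherin fragments numbered 369 and 664, a 2.24-fold higher share in the knockdown library (1.97 to 2.55), although exons shared within the clusters make the split among members uncertain. Of 86 cancer-testis and germline genes, 5 were measured (median 0.45, percentile 95.1), with 1 at least 2-fold higher and 0 lower. The list stood apart as higher with no filter on low values (median 0.0426 over 41 members, percentile 99.5) and with a pseudocount of 5 (percentile 97.8). MAGEB17 was 11.2-fold higher (6.29 to 21.6), MAGEB1 2.72-fold higher (1.59 to 4.80), MAGEB2 1.37-fold higher (1.30 to 1.45) and MAGEA2 2.29-fold lower (1.36 to 4.03), and members of this family can share reads. Of 17 genes derived from endogenous retroviruses, 6 were measured (median 0.16, percentile 78.1), with ERVK13-1 4.06-fold higher (3.41 to 4.84) and ERVMER34-1 3.39-fold lower (2.75 to 4.21). Imprinted genes had a median of 0.36 over 11 members (percentile 94.9), with 2 at least 2-fold higher, NAP1L5 (4.03-fold, 2.95 to 5.60) and NNAT (4.14-fold, 2.13 to 8.68), and 0 lower, and stood apart with a pseudocount of 5 (percentile 98.4). HOX genes did not stand apart (median 0.05 over 21 members, percentile 69.2, and -0.05 with equal FPKM totals), with 2 at least 2-fold higher, HOXB9 (3.67-fold, 3.24 to 4.18) among them, and 0 members at least 2-fold lower.

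Replication-dependent histone genes were higher, while the replication genes were lower. Of 18 measured members, 11 were at least 2-fold higher and 3 at least 2-fold lower (median 1.60, percentile 100). H2BC4 and H2AC6 were 28.3-fold (11.8 to 89.0) and 10.7-fold (8.25 to 14) higher, beside H2BC5 and H1-2. The 3 lower members were H2AC14, H4C1 and H2BC17 (log2 ratios -1.64, -1.63 and -1.15), named after their values were seen. Summed over all 66 listed genes, histone fragments numbered 903 in the control and 4668 in the knockdown library, a 6.43-fold higher share (5.98 to 6.91). A few members weigh heavily in this sum: H1-2 had 111 and 1495 fragments and H2BC5 51 and 810. With no filter on low values the median was 0.15 over 49 members (percentile 100). It was 0.60 with a pseudocount of 5, and 2.94 over 5 members with a filter at 5 FPKM. These genes have near-identical copies and mRNAs that mostly lack a poly(A) tail, so their split among members is uncertain.

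Wnt target genes were lower by a small median of -0.35 over 19 measured members (percentile 2.33), with 3 at least 2-fold lower and 1 higher. CEMIP, AXIN2, the feedback inhibitor of the pathway, and SLC12A2 were 3.05-fold (2.58 to 3.63), 2.62-fold (2.25 to 3.05) and 2.34-fold (2.11 to 2.60) lower. CCND1, which encodes cyclin D1, was 2.14-fold higher (2.08 to 2.21) and SOX9 1.60-fold higher (1.5 to 1.71), while MYC was at 56.1 and 52.1 FPKM. LGR5 and ASCL2, markers of intestinal stem cells, had at most 6 fragments in either library. The Wnt list no longer stood apart with a pseudocount of 5, a filter at 5 FPKM, equal FPKM totals or without low-count and overlapping genes, at percentiles of 2.65 to 6.19. Colonic differentiation genes were mostly unmeasured, with 8 of 54 past the filter (median -0.35, percentile 8.35). Of these, KLF4 was 2.14-fold higher (1.96 to 2.33), KRT8 1.45-fold lower (1.42 to 1.47), CA2 1.42-fold lower (1.22 to 1.65) and SLC26A2 1.66-fold lower (1.47 to 1.89).

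Neural stem and progenitor genes were lower in the knockdown library, with a median of -0.50 over 12 measured members of 33 (percentile 0.83), 2 at least 2-fold lower and 0 higher. With no filter on low values the median was -0.10 over 22 members (percentile 2.49). LHX2 and ZIC2, transcription factors of the early brain, were 3.35-fold (2.44 to 4.67) and 2.22-fold (1.93 to 2.56) lower. SIX3 was 2.78-fold lower (1.71 to 4.69), the intermediate filament gene NES 1.80-fold lower (1.56 to 2.07), MSI1 1.53-fold lower (1.28 to 1.82), SOX4 1.35-fold lower (1.30 to 1.40) and HES1 1.49-fold lower (1.21 to 1.83). FGFR1 and BMI1 were 1.65-fold (1.54 to 1.76) and 1.40-fold (1.26 to 1.55) higher, and SOX1 and OTX2 were listed at 0 in both libraries. Neuronal differentiation genes went both ways (median -0.02 over 15 of 50 members, percentile 48.9), with 1 at least 2-fold higher and 1 lower. With a filter at 5 FPKM, 8 members were left and stood apart as lower (median -0.48, percentile 1.98). SCG2, a secretory granule protein gene, was 3.47-fold lower (3.09 to 3.90), L1CAM, an adhesion molecule, 2.98-fold higher (2.56 to 3.48), MAP1B 1.76-fold higher (1.55 to 2.0) and ENO2 1.91-fold lower (1.70 to 2.15). TUBB3 was at 1.54 and 1.79 FPKM, a ratio whose interval included 1 (1.16-fold, 0.950 to 1.43).

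Genes of epithelial-mesenchymal transition were higher, with a median of 0.67 over 16 measured members of 37 (percentile 99.9), 6 at least 2-fold higher and 0 lower. With no filter on low values the median was 0.09 over 33 members (percentile 99.6). The matrix gene CCN2 was 11.8-fold higher (7.99 to 18.1), and the receptor tyrosine kinase gene AXL 3.87-fold higher (3.51 to 4.28). SNAI2, which encodes the transcription factor Slug, had 0 fragments in the control and 124 in the knockdown library, at least 51.4-fold higher against a floor of 3 fragments. FN1, CALD1, TPM2 and TAGLN were lower, with log2 ratios of -0.67, -0.70, -0.43 and -0.37, and were named after their values were seen. The other 12 measured members were higher. Epithelial junction genes did not stand apart: 4 of 31 measured members were at least 2-fold higher and 0 lower (median 0.27, percentile 92.4). The median was 0.14 with equal FPKM totals, 0.17 with centring, 0.15 with a pseudocount of 5 and 0.13 with no filter on low values. The claudin genes CLDN3 and CLDN4 were 4.34-fold (3.83 to 4.93) and 2.30-fold (2.20 to 2.40) higher, the membrane protease gene PRSS8 4.15-fold higher (3.76 to 4.60) and the keratin gene KRT7 2.61-fold higher (2.26 to 3.01).

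Interferon-stimulated genes did not stand apart (median 0.01 over 23 measured members, percentile 54.9, and -0.10 with equal FPKM totals). BST2 and SAMD9 were 3.98-fold (2.38 to 6.94) and 2.68-fold (2.38 to 3.02) higher, and IFITM2 and OAS3 2.42-fold (2.06 to 2.86) and 2.70-fold (2.43 to 3.0) lower, the 4 members past 2-fold on the log2(FPKM + 1) scale. Inflammatory genes of the NF-kB pathway were higher, with a median of 0.48 over 15 members (percentile 99.3), 3 at least 2-fold higher and 0 lower. The neutrophil chemokine genes CXCL8 and CXCL1 were 19.3-fold (9.90 to 43.2) and 11-fold (4.72 to 31.3) higher from 9 and 6 fragments in the control, and the NF-kB subunit genes RELB and NFKB2 3.72-fold (3.11 to 4.47) and 1.77-fold (1.65 to 1.89) higher. The NF-kB list no longer stood apart with a pseudocount of 5 (percentile 97.2) or with a filter at 5 FPKM (92.8, 8 members). Of 19 antigen presentation genes, 6 were measured (median 0.44, percentile 94.8), with HLA-C 3.53-fold higher (2.42 to 5.26), B2M 1.5-fold higher (1.38 to 1.62) and 0 members at least 2-fold lower. HLA-B and CANX were at very low values for abundant genes. Low values in this list are thus not evidence of low expression, and its folds may rest on a part of the reads.

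Cytosolic ribosomal protein genes were lower by a small amount, with a median of -0.38 over 77 measured members (percentile 0), 3 at least 2-fold lower and 0 higher. RPSA was 2.13-fold lower (2.09 to 2.18), RPL7L1 2.33-fold (2.17 to 2.51), RPS25 3.86-fold (2.19 to 7.25) and RPL37A 1.98-fold lower (1.90 to 2.06), and pseudogene copies make single members uncertain. Nuclear-encoded oxidative phosphorylation genes had a median of -0.20 over 59 members (percentile 1.03), with 1 at least 2-fold higher, NDUFA4 (2.48-fold, 2.32 to 2.64), and 0 lower. COX8A and NDUFB6 were 1.76-fold (1.59 to 1.94) and 1.60-fold (1.40 to 1.83) lower. This list's percentile was 3.62 once the trend with GC content and length was removed, and its median was -0.33 with equal FPKM totals. Mitochondrially encoded mRNAs had a median of 0.43 over 13 members (percentile 96.3, and 98.2 with a filter at 5 FPKM), with MT-ND3 and MT-ND2 2.13-fold (2.09 to 2.16) and 2.06-fold (2.04 to 2.08) higher and 0 members at least 2-fold lower. Mitochondrial genes together took 8.64% of fragments in the control and 9.86% in the knockdown library.

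Housekeeping reference genes did not stand apart (median -0.07 over 26 members, percentile 16.8). Beside PGK1, EMC7 was 2.63-fold higher (2.35 to 2.95), and GUSB was 2.32-fold lower (2.02 to 2.68). Of 10 fibroblast markers, 1 was measured, COL1A1 at 3.72 and 5.53 FPKM, and of 10 endothelial markers, 1 was measured, ESAM at 2.75 and 3.99 FPKM. The 15 blood and immune markers, of which 0 passed the filter, had 33 fragments in the control and 80 in the knockdown library. Of 10 markers of an embryonic kidney line, 3 were measured and all 3 were lower in the knockdown library: PAX2 (2.43-fold, 1.93 to 3.09), HOXA9 (1.82-fold, 1.63 to 2.03, from 20 FPKM in the control) and GATA2 (1.60-fold, 1.42 to 1.80, from 10.3 FPKM in the control).

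**Figure D3:**
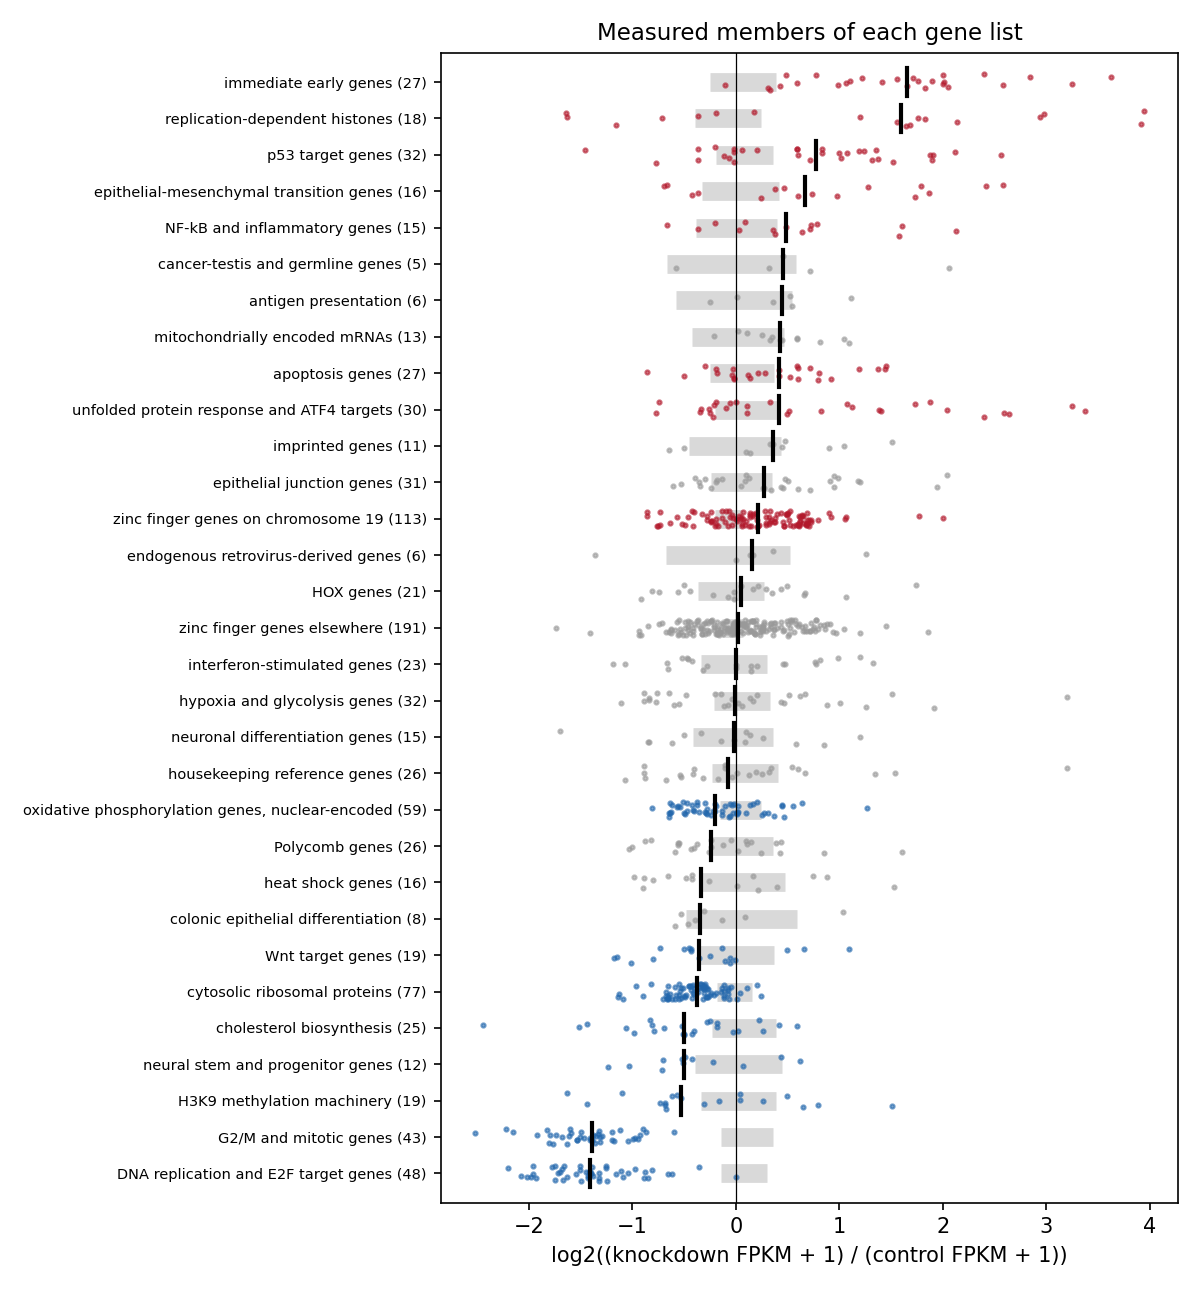
log2 ratio of knockdown to control (FPKM + 1) of each measured member (points, number in parentheses) of the 31 lists with at least 5 measured members, with the list median (black bar) and the central 95% of medians of 10000 random lists matched on expression (grey band). Lists whose median lies above the band are red and those below it blue; the medians run from 1.66 for immediate early genes to -1.41 for DNA replication and E2F target genes.

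Of the 31 lists with at least 5 measured members, 16 stood apart, 8 higher and 8 lower in the knockdown library. For lists of genes drawn at random, 1.55 would. Genes of a list can vary together and lists share members, so 1.55 is no chance rate for a difference between single cultures. Of the 16 lists that stood apart, 10 kept their side under each of the settings tried.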

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

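Removal of the trend with GC content and length, and leaving out low-count and overlapping genes, were chosen after seeing the data, as was the background of chromosome 19 genes, and the other settings before. SETDB1 had a log2 ratio of -2.22, and was lower in the knockdown library under the settings run for it (both pseudocounts, equal totals and centring), with values of -3.40 with a pseudocount of 0.1 and -0.99 with a pseudocount of 5, as the pseudocount outweighs low values. The counts of 822 genes higher and 657 lower became 389 and 192 with a pseudocount of 5, 2022 and 1776 under a 1.5-fold rule, and 94 and 30 under a 4-fold rule. They became 1127 and 1062 with a pseudocount of 0.1, and 659 and 393 with a filter at 5 FPKM. Equal FPKM totals gave 632 higher and 868 lower, and centring 673 and 838, so which direction held more genes depended on scaling. Of 243 recomputed list medians, 219 stayed apart or stayed not apart, 18 no longer stood apart and 6 newly did. The sign of the median turned in 15, over 6 lists that did not stand apart (heat shock, HOX, interferon, hypoxia, neuronal and zinc finger genes elsewhere). The unfolded protein response and ATF4 list no longer stood apart with pseudocounts of 0.1 and 5 (medians 0.42 and 0.31), no filter (0.11), a filter at 5 FPKM (0.22), equal totals (0.27), GC and length removed (0.35) and without low-count and overlapping genes (0.11). The same held for Wnt targets with a pseudocount of 5 (-0.18), a filter at 5 FPKM (-0.28), equal totals (-0.46) and without low-count and overlapping genes (-0.34). It held for apoptosis genes with a pseudocount of 5 (0.21), no filter (0.22) and a filter at 5 FPKM (0.42), and for NF-kB genes with a pseudocount of 5 (0.22) and a filter at 5 FPKM (0.54). It also held for chromosome 19 zinc finger genes with a filter at 5 FPKM (0.45) and oxidative phosphorylation with GC and length removed (-0.16). Newly apart were germline genes with a pseudocount of 5 (0.30) and no filter (0.0426), imprinted genes with a pseudocount of 5 (0.27), neuronal genes (-0.48) and mitochondrially encoded mRNAs (0.43) with a filter at 5 FPKM, and Polycomb genes with equal totals (-0.36). For these lists the cause was not tested. Depth limits genes near the floor of 3 fragments, which for a gene of 1 kb is 0.168 FPKM in the control and 0.209 FPKM in the knockdown library. No paired analysis was possible because each group has 1 library.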

Other observations

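The tests in this part were chosen after the data were seen, except that of the library number. The GC content and length test was chosen after the data were seen but before its own result was. Genes of Golgi traffic and vesicle coats were higher in the knockdown library beside ARF4 and CREB3. Of 71 measured members of a list written after the top genes were seen, 33 were at least 2-fold higher and 2 lower, with a median log2 ratio of 0.95. Over the 45 measured members that had not been inspected when the list was written, 20 were at least 2-fold higher and 2 lower, with a median of 0.93 at percentile 100, so the hypothesis of coat and Golgi genes higher as a set may hold beyond the genes that led to it. The genes named in this paragraph were chosen after their values were seen. The KDEL receptor genes KDELR3 and KDELR2, which return proteins to the endoplasmic reticulum, were 6.12-fold (5.54 to 6.77) and 3.92-fold (3.74 to 4.10) higher. YIPF2, YIPF5 and the golgin gene GOLGA3 were 6.84-fold, 5.39-fold and 5.58-fold higher, the ARF activator gene GBF1 2.99-fold, and the COPI coat genes COPA and COPB1 2.52-fold and 2.24-fold, while the coat gene COPZ1 was 1.51-fold lower. The endoplasmic reticulum chaperone gene HSPA5 was 3.33-fold (3.27 to 3.39) and its cofactor gene DNAJB9 4.76-fold (4.09 to 5.56) higher. The iron storage genes FTL and FTH1 were 3.80-fold (3.73 to 3.87) and 2.47-fold (2.41 to 2.53) higher, and the heme oxygenase gene HMOX1 6.12-fold (5.50 to 6.82).

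Of 752 long non-coding RNA genes with a mean of at least 1 FPKM, 68 were at least 2-fold higher in the knockdown library and 48 lower. PINCR, a non-coding RNA induced by p53, had 3 and 84 fragments (34.8-fold, 11.5 to 172). GAS6-DT was 23.6-fold higher (12.6 to 50.1) beside its neighbour GAS6 (6.86-fold, 6.33 to 7.44), and LINC00857 4.04-fold higher (3.27 to 5.00). These genes were chosen after their values were seen. Among clustered protocadherins, PCDHB10 had 2 and 50 fragments (31.1-fold, 8.17 to 264), also chosen after. Median log2 ratios of the 23 chromosomes ran from -0.07 on chromosome 21 to 0.14 on chromosome 19.

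A hypothesis was that loss of SETDB1 turns on genes without reads in the control. With the control thinned to the scaling total of the knockdown library, which left it 12006390 assigned fragments against 12790965, 68 genes had 0 fragments in the control and at least 10 in the knockdown library, and 69 the reverse. The ratio was 0.986 (0.695 to 1.40), below a cut-off of 1.5 that was set after the data were seen. This interval comes from the counts of genes and treats genes as independent. Genes turned off for other reasons could offset genes turned on, so the ratio cannot decide the hypothesis. At the level of annotated genes no excess of genes turned on was found, while repeats outside genes were not measured.

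Genes of the cell cycle were lower in the knockdown library. GC content or length as the cause is argued against: the median over both cell cycle lists was -1.40 before and -1.43 after its trend with them was removed, with 75 of 91 members at least 2-fold lower in each case. A scaling shift would move the other protein-coding genes as well, whose median was 0.0299. With the number of libraries per group at 1, an effect of the knockdown and a difference between single cultures cannot be told apart. The control carried an empty vector, so an effect of the shRNA other than on SETDB1 cannot be told apart either. Off-target matches were not searched, because the labels do not give the shRNA sequence. The same limits hold for the other differences between these libraries.

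Replication-dependent histone genes were higher while the replication genes were lower. More cells in S phase would raise the replication list, whose median was -1.41. A weaker selection of polyadenylated RNA could raise small non-coding RNA genes, whose share was 0.667 of the control (0.628 to 0.708). It was 0.905 (0.848 to 0.966) without RN7SL1, which had 899 and 64 fragments. These small RNA genes had only 3077 fragments in the control and 1650 in the knockdown library. Whether poly(A) RNA was selected is not given either, so their share cannot decide that explanation. Polyadenylated histone transcripts of cells outside S phase are another possible explanation, which positions of reads in the histone genes would test.

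PGK1 was 9.29-fold higher in the knockdown library. A gain of its chromosome region is argued against by its neighbours COX7B, MAGT1, TAF9B, ATRX and ATP7A within 500 kb, with a median log2 ratio of 0.13. A rise of glycolytic enzymes together is argued against by the median of -0.60 over 15 other enzymes, with GAPDH 1.84-fold lower (1.81 to 1.88), chosen after its values were seen. The pLKO.1 vector carries a PGK promoter, so reads from the vector could be among the 62725 PGK1 fragments of the knockdown library. The control cells carried the same vector backbone and had 8398 fragments, so the vector would account for the difference only with more vector RNA in the knockdown cells, which cannot be told apart because the values give no positions within the gene.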
